A study of Mus musculus with 17 samples.

How the data were processed

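RNA was measured in myeloid cells sorted from female BALB/c mice, some of which carried a tumor of 4T1-luc cells, a luciferase-expressing mouse mammary carcinoma line. Per the labels' protocols, 100000 cells were injected into a mammary fat pad and tumors were taken at a size of 1 cm. Libraries were 3'-end mRNA libraries with a sample barcode and a unique molecular identifier. Tumor and normal fat pad were digested with different collagenase mixtures, while marrow was flushed from the bones and treated with red cell lysis buffer, per the labels' protocols. The labels give an age of 8 weeks for the tumor-bearing groups and 12 weeks for the healthy groups, although the design text calls the healthy mice age-matched.

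The deposited values are raw counts in 1 table of 24421 rows. Per the submitters' processing notes, bcl2fastq, STAR 2.4.2a and HTSeq were used with genome build mm10. Whether molecular identifiers were collapsed, the annotation, the strand setting and the filter on genes are not given in the sources used here. Gene symbols fill the upper 10207 rows, and the 11 libraries of batch 1 have counts in those rows alone. The 6 libraries of batch 2 (BMDM_H replicates 5 to 8 and both MGM libraries) have counts in all rows, but in another order. Over the rows with a symbol, Spearman correlations between batch 1 and batch 2 libraries ran from -0.02 to 0.0 in 66 pairs. Within batch 1 BMDM_H they were 0.92 to 0.96, and within batch 2 BMDM_H 0.78 to 0.93. The symbols were therefore used for batch 1 only. Batch 2 counts were analysed as rows without a gene name, and no row was assigned to a gene by its position. The 14214 rows without a symbol hold no batch 1 count. Spreadsheet conversion had turned 17 symbols into dates, and these are not named.

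The intended single fit over all 17 libraries with batch as a term was replaced by 1 fit per batch. Gene by gene, TAM against MGM, the difference between the tissue steps, batch 2 against batch 1 within BMDM_H and the overlap of the tissue steps were not computed, since they need rows matched across batches. The comparison of TAM with BMDM_H was added after the data had been examined. In each fit, edgeR 4.0.16 in R 4.3.3 was run with filterByExpr, TMM factors, estimateDisp, glmQLFit and glmQLFTest, and Benjamini-Hochberg adjusted p-values under 0.05 were called. Of the batch 1 genes 7518 were tested, and of the batch 2 rows 10615. Standard errors (SE) are the unshrunken log2 fold change divided by the square root of the quasi-likelihood F. CPM values are counts scaled to a common library total with the TMM factors, and their errors are standard deviations (SD). Because the batch 1 table holds part of the genes, CPM and totals refer to the genes in it.

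Before the data were examined, 38 gene lists were fixed, covering functions, sort antigens, stress, quality and other cell types. Their 512 entries included 407 with a matching symbol. Lists with at least 4 tested members (27 of them) were tested with camera in limma 3.58.1 with a preset correlation of 0.01, and again with an estimated correlation and with fry. Another 9 lists were added after the calls had been seen. Named genes follow a rule fixed beforehand. From calls with at least 30 CPM in the higher group, at least 10 counts in each group and no overlap between the libraries of the groups, the 6 largest rises and the 6 largest falls were taken, without predicted genes. Up to 3 genes per direction with 0 counts in the lower group were added, with the fold as a lower bound against a floor of 3 counts over the group. The antigens of the sort and up to 4 members of each list with the smallest p were added as well.

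Total counts ran from 387940 to 3747929 in batch 1 and from 331417 to 5107793 in batch 2. Floors cover counting error only. Replicates of a group differed by more than sampling noise in each pair, with chi-square per degree of freedom from 2.67 to 29.24, so each library counted as 1 sample. The labels do not say that replicates are separate mice, so p-values measure the spread between these samples, which may be technical. BMDM_T and BMDM_H libraries with the same replicate number deviated together from their group means (r = 0.22, 0.24, 0.13 and 0.13 across genes), which met the limit of 0.1 set for treating the numbers as pairs. The labels do not say what the numbers share. Although the limit was met, the main fit did not use the numbers, and they were a block only in an alternative. For BMDM_T against BMDM_H that alternative gave 510 calls and 12 lists, against 362 calls and 9 lists in the main fit. For TAM and BMDM_T the values were 0.02, -0.03 and 0.08.

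The procedure was tested on simulated data with 200 changed genes or rows. It recovered 56% of 2-fold and 93% of 4-fold changes for BMDM_T against BMDM_H, 61% and 94% for TAM against BMDM_T, and 50% and 93% for TAM against BMDM_H. For MGM against BMDM_H it recovered 0% of 2-fold and 22.5% of 4-fold changes. False calls numbered 0 to 14 per run, with 14 for 4-fold changes in BMDM_T against BMDM_H. The simulated changes were set around 1 mean profile and were far fewer than the calls between TAM and marrow. Recovery and scaling under such wide differences were therefore not tested. Alternatives were DESeq2 1.42.0, limma-voom, relative log expression factors, total counts only, no low-count filter, a filter at 10 CPM in 2 libraries, glmTreat against a fold of 1.5, only the libraries of the groups compared, the replicate number as a block, and each library left out in turn. Chosen after seeing the data were thinning to the smallest total, leaving out BMDM_H replicates 3 and 4 together, and scaling factors from genes outside the granule lists and the 20 most abundant genes. Coordinates are from GENCODE M21 on the mm10 assembly, by symbol.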

Results

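Gene expression was measured in 17 libraries from 4 groups of sorted cells. Tumor-associated macrophages (TAM) were CD11b+ Gr1- F4/80+ cells from tumors, with 3 libraries and total counts of 1748338 to 3747929. Marrow cells of mice with a tumor, labelled as monocytes (BMDM_T), were CD11b+ Gr1+ F4/80low cells, with 4 libraries of 931278 to 1218977 counts. The same marrow gate in healthy mice (BMDM_H) gave 4 libraries of 387940 to 1286844 counts in batch 1 and 4 of 331417 to 5107793 in batch 2. Mammary gland macrophages (MGM), sorted as CD11b+ F4/80+ cells from normal fat pad, had 2 libraries of 3850345 to 4516182 counts. The 11 libraries of batch 1 could be compared by gene. The first principal component held 72.4% of their variance and parted TAM from marrow, and the second held 8.2%.

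**Figure D1:**
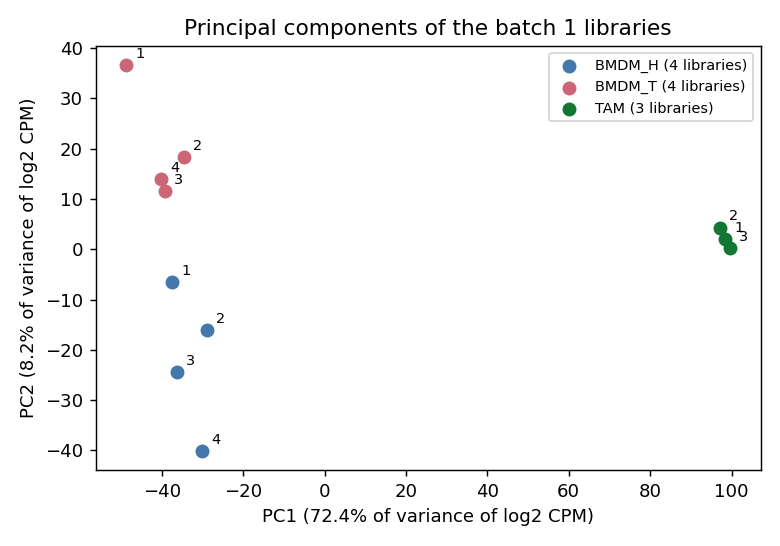
Principal components of log2 CPM over 7518 genes in the 11 batch 1 libraries, with 1 point per library labelled by its replicate number and colored by group. The TAM libraries lie at 97.1 to 99.7 on the first component, and the marrow libraries lie between -48.8 and -28.8.

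BMDM_T against BMDM_H compares the marrow cells that the labels call monocytes between mice with and without a tumor. All BMDM_T libraries have a label age of 8 weeks and all BMDM_H libraries 12 weeks. Effects of the tumor and of label age therefore cannot be told apart here. Neutrophil genes were the most abundant transcripts in both groups, with S100a9 the top gene in 7 of the 8 libraries and Camp in the other, and Ngp at 27420 CPM in BMDM_T and 33670 CPM in BMDM_H, against 115 and 247 CPM for the monocyte gene Ccr2. Shares of monocytes and neutrophils in the sorted cells were not analysed here, so changes below are those of the sorted cells as a whole. Saa3, an acute-phase serum amyloid gene, rose 54.4-fold in BMDM_T, from 4.72 ± 5.54 to 185 ± 68.2 CPM (SD, n = 4 per group; log2 fold change 5.76 ± 0.43 SE, adjusted p = 5.21e-08, and 6.48 without BMDM_H replicate 4, which had 13.0 CPM against 1.61 to 2.39 in the others). Igfbp6, an insulin-like growth factor binding protein, rose 48.5-fold to 147 ± 20.0 CPM, and Ggt1, a gamma-glutamyltransferase, rose 17.8-fold to 123 ± 50.9 CPM. The interferon-inducible membrane gene Ifitm1 reached 1001 ± 433 CPM (17.5-fold), the chemoattractant Prok2 253 ± 108 CPM and the stefin A gene Stfa3 130 ± 89.6 CPM, both 15.4-fold higher. Among genes with at least 30 CPM in the higher group and at least 10 counts in each, the largest falls were in Car2, a carbonic anhydrase, from 76.0 ± 45 to 8.02 ± 4.47 CPM (8.46-fold), and in the water channel Aqp1 (8.40-fold), followed by Thbs1 (6.88-fold), Clec2i (4.31-fold), Cd5l (4.29-fold) and the ficolin Fcna (4.24-fold). Cldn13 and Kel, a red cell antigen gene, had 0 counts in BMDM_T and were at least 35.2-fold and at least 14.0-fold lower than in BMDM_H. Without BMDM_H replicates 3 and 4, the libraries with the lowest totals, Cd5l had an adjusted p = 0.0641.

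In mm10, Saa3 lies on chromosome 7 (46711998 to 46715700, minus strand), Igfbp6 on chromosome 15 (102144362 to 102149511, plus strand), Car2 on chromosome 3 (14886273 to 14900770, plus strand) and Aqp1 on chromosome 6 (55336432 to 55348555, plus strand). All 4 are protein-coding genes.

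Genes of the azurophil granule of neutrophil and monocyte precursors rose together. Of 10 members 8 were higher and 0 lower, with a median log2 fold change of 1.12 (camera adjusted p = 1.45e-22, and adjusted p = 0.000247 with an estimated correlation). The protease genes Prtn3 (log2 fold change 2.05 ± 0.18 SE, 5563 against 1338 CPM), Elane (1.59 ± 0.18) and Ctsg (1.69 ± 0.23) and the myeloperoxidase gene Mpo (1.79 ± 0.19) were among them. Calr, also among the 8, is a chaperone gene that is not specific to granules. Its call was lost in several alternatives, such as total counts only (adjusted p = 0.0563) and without BMDM_H replicate 1 (0.0538). Of 16 specific granule and mature neutrophil genes 4 rose, including the chemokine receptor Cxcr2 (1.48 ± 0.16) and Ifitm6 (1.32 ± 0.21), and 12 did not pass. The list passed with camera (adjusted p = 2.01e-05) but had an adjusted p = 0.281 with an estimated correlation. These granule genes were abundant in both marrow groups, with the specific granule list summing to 193500 ± 16900 CPM in BMDM_T and 188800 ± 31130 CPM in BMDM_H.

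Glycolytic genes also rose as a list (adjusted p = 2.01e-05, and adjusted p = 0.0456 with an estimated correlation). Of its 13 members 2 passed over all genes and 7 when adjusted over the list alone. They were the lactate exporter Slc16a3 (log2 fold change 1.27 ± 0.21 SE) and the glucose transporter Slc2a1 (1.5 ± 0.26). Among 11 hypoxia-responsive genes 4 rose and 0 fell, among them Ankrd37 (2.97 ± 0.31) and Mif (1.59 ± 0.19), with a list median of 0.04 and an adjusted p = 0.00359, and adjusted p = 0.281 with an estimated correlation. In the inflammatory list 3 of 15 genes rose, including Saa3 and the nitric oxide synthase Nos2 (5.22 ± 0.97, 14.8 against 0.465 CPM), and the list did not pass (median -0.2, adjusted p = 0.196), although it had an adjusted p = 0.0209 without BMDM_T replicate 4. In BMDM_H, Nos2 was found in replicate 3 alone (1.86 CPM, others 0), so the size of its rise is uncertain.

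Markers of red cell precursors fell in BMDM_T. All 5 tested members were lower, with a median log2 fold change of -5.31 (camera adjusted p = 6.75e-14, and adjusted p = 0.0456 with an estimated correlation), and their list summed to 154 ± 85.2 CPM in BMDM_H and 10.3 ± 6.66 CPM in BMDM_T. The anion exchanger gene Slc4a1 had 92 counts over the BMDM_H libraries and 1 over BMDM_T, a ratio of 110 (95% exact counting interval 19.3 to 4390). Alas2 and Ermap also had 1 count each over BMDM_T, so the size of the list median is uncertain. Car2 and Car1 had 34 and 7 counts in BMDM_T. As scaled ratios of counts summed over each group, they were 7.28-fold and 8.89-fold higher in BMDM_H. The fit, which takes each library as a sample, gave 8.46-fold for Car2. Ermap had an adjusted p = 0.11 with limma-voom. Of 10 genes of tissue-resident macrophages 3 fell, and 7 did not pass (list adjusted p = 1.38e-05, and adjusted p = 0.209 with an estimated correlation). Of these 3, Fcna kept its call in every alternative, Cd163 (-3.13 ± 0.62) had an adjusted p = 0.0622 with limma-voom, and Cbr2 had 0.148 with limma-voom, 0.161 after thinning, 0.0836 against a fold of 1.5, 0.0764 without BMDM_H replicates 3 and 4, and, with 1 library left out, 0.0512 and 0.0959 (BMDM_H replicates 1 and 2) or 0.0817 and 0.066 (BMDM_T replicates 2 and 3). The complement genes C1qa (-1.71 ± 0.31), C1qb (-1.46 ± 0.26) and C1qc (-1.25 ± 0.31) fell as well, but the macrophage core list, with 3 lower and 1 higher of 14, did not pass (adjusted p = 0.0791), nor did the complement list (adjusted p = 0.377). The fall of C1qc had an adjusted p = 0.0778 without BMDM_H replicate 4 and 0.0636 without BMDM_T replicate 1. Without BMDM_H replicates 3 and 4 together, C1qa had 0.0611 and C1qc 0.176, and with DESeq2 C1qc had 0.0512. The macrophage core list had an adjusted p = 0.046 without BMDM_H replicate 3 and 0.0348 without BMDM_T replicate 2. It had 0.0456 after thinning, 0.0384 without BMDM_H replicates 3 and 4, and 0.0457 with fry, but 0.281 with an estimated correlation.

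Several monocyte genes were lower in BMDM_T. Ccr2, the chemokine receptor of classical monocytes, fell from 247 to 115 CPM (log2 fold change -1.11 ± 0.17 SE), and Ms4a4c by 1.62 on the log2 scale, while Ifitm6 rose. The monocyte list, with 4 lower and 2 higher of 12, had an adjusted p = 0.0614, and adjusted p = 0.478 with an estimated correlation. It had 0.000107 without BMDM_H replicates 3 and 4, 0.0271 after thinning, 0.0329 without the low-count filter, 0.0103 without BMDM_H replicate 3, 0.00861 without BMDM_H replicate 4 and 0.0274 without TAM replicate 3. Ifitm6 is also in the specific granule list. Interferon-stimulated genes included 3 lower of 14, among them Bst2 (-1.25 ± 0.21), with a list adjusted p = 0.0115 that became 0.403 without BMDM_H replicate 1, and an adjusted p = 0.517 with an estimated correlation. The interferon list also had 0.207 with fry and 0.0514 after thinning. Of 16 dissociation and stress genes 4 fell, including Nr4a1 (-1.83 ± 0.24) and Atf3 (-1.84 ± 0.28), and 1 rose (list adjusted p = 0.0118, and adjusted p = 0.478 with an estimated correlation). That list had an adjusted p = 0.271 without BMDM_T replicate 4, 0.0607 without BMDM_H replicate 3 and 0.195 with fry.

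Among the transcripts of the sort antigens, Itgam, which encodes CD11b, had 558 ± 37.6 CPM in BMDM_T and 580 ± 78.6 CPM in BMDM_H (adjusted p = 0.899). Adgre1, which encodes F4/80, fell by 1.12 on the log2 scale (SE 0.32, adjusted p = 0.0435) and Ly6c2 by 0.79 (SE 0.22, adjusted p = 0.0382). Neither call was stable, since without BMDM_H replicate 1 the adjusted p was 0.143 for Adgre1 and 0.153 for Ly6c2. Ly6c1 and Ptprc did not pass (adjusted p = 0.0845 and 0.646), although Ly6c1 had 0.0389 without BMDM_H replicate 3 and 0.0143 without BMDM_H replicates 3 and 4. The list of these antigens passed with camera (adjusted p = 0.0122) but had an adjusted p = 0.187 with an estimated correlation, and an adjusted p = 0.0552 without BMDM_H replicate 1.

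In total 362 of 7518 genes differed between BMDM_T and BMDM_H, 212 higher and 150 lower. Leaving out BMDM_H replicates 3 and 4, the libraries with the lowest totals in batch 1, gave 179 calls, and leaving out BMDM_H replicate 2 gave 238. With total counts as the only scaling, 155 genes were higher and 218 lower. Of the 27 lists tested 9 passed, and with an estimated correlation 3 of them did, the primary granule, erythroid and glycolysis lists. Lists that did not pass included MHC class II presentation (adjusted p = 0.447), interferon gamma response (0.864), lysosome (0.70), chemokines (0.0614), cell cycle (0.241), DNA methylation machinery (0.443), transcription factors (0.655), lipid handling (0.472), lipid-associated macrophage genes (0.488), alternative activation (0.341), angiogenesis and matrix (0.447) and immune checkpoints (0.441). With replicate numbers as blocks, the chemokine list passed (adjusted p = 0.0427), and it had 0.0156 without BMDM_H replicate 1, 0.0128 without BMDM_T replicate 2 and 0.046 without TAM replicate 3. In the main fit it had an adjusted p = 0.515 with an estimated correlation.

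**Figure D2:**
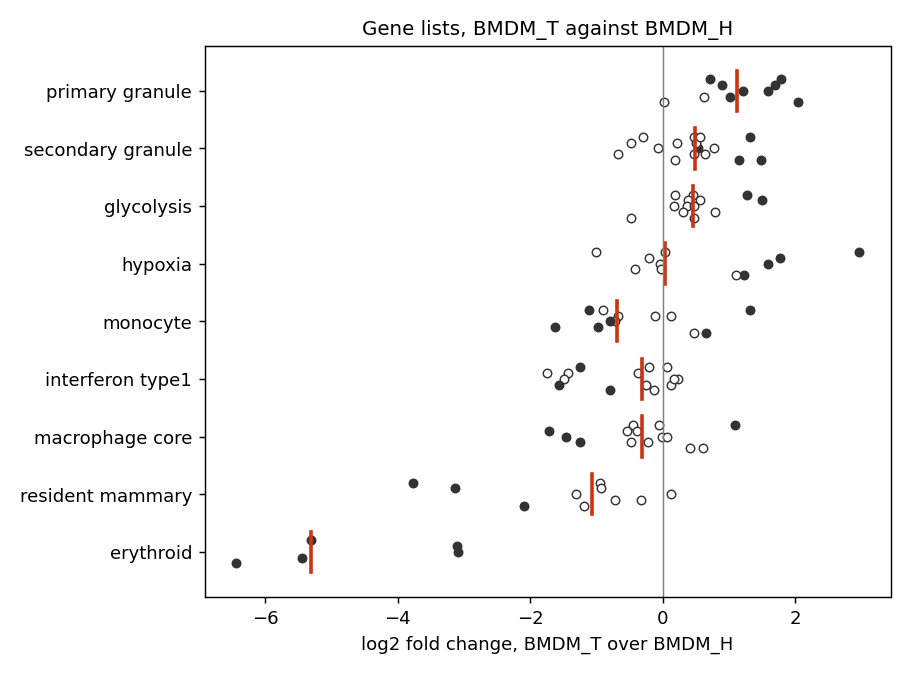
Log2 fold change of BMDM_T over BMDM_H (horizontal axis) for each tested member of 9 gene lists, with filled points for genes with an adjusted p under 0.05, open points for the rest and a red bar at the list median. The erythroid median lies at -5.31, on a gene with 1 count over BMDM_T, and the primary granule median at 1.12.

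TAM against BMDM_T compares tumor macrophages with the marrow cells of tumor-bearing mice. Arg1, the arginase of alternatively activated macrophages, rose 215-fold in TAM, from 9.04 ± 6.69 (SD, n = 4) to 1957 ± 604 CPM (SD, n = 3; log2 fold change 7.74 ± 0.47 SE, adjusted p = 2.4e-11). The signaling regulator Rgs1 rose 123-fold, Zmynd15 119-fold and the activation marker Cd83 96.6-fold. The complement genes C1qa and C1qb rose 91.5-fold and 94.5-fold, to 17920 ± 2885 and 5842 ± 220 CPM. Among genes with at least 10 counts in each group, the largest falls were in the neutrophil genes Cd177 (701-fold), Ltf (655-fold), Lcn2 (581-fold), Asprv1 (527-fold), Mpo (502-fold) and Ngp (486-fold), with Ngp going from 27420 ± 3269 to 56.0 ± 15.8 CPM. In TAM, 0 counts were found for Prg2 of eosinophil granules, Vpreb3 of B cell precursors and Prss34 of basophils, which were at least 451-fold, at least 308-fold and at least 263-fold lower than in BMDM_T. Cox4i2 and the prostaglandin synthase gene Hpgds had 0 counts in BMDM_T and were at least 18.1-fold and at least 17.8-fold higher in TAM. In mm10, Arg1 lies on chromosome 10 (24915221 to 24927484, minus strand), C1qa on chromosome 4 (136895917 to 136898803, minus strand), Ltf on chromosome 9 (111019271 to 111042767, plus strand) and Cd177 on chromosome 7 (24743983 to 24760311, minus strand).

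All 14 macrophage core genes rose (median log2 fold change 3.31, camera adjusted p = 1.34e-18, and adjusted p = 0.00029 with an estimated correlation). Apoe, an apolipoprotein of macrophage lipid efflux, reached 35280 CPM against 1795 (4.30 ± 0.19 SE), and Cd14 rose by 4.34 ± 0.21. Lysosomal genes rose in 18 of 20 cases (adjusted p = 1.52e-08), with the cathepsins Ctss (4.03 ± 0.27) and Ctsl (3.35 ± 0.21) among them. Of 11 MHC class II presentation genes 10 rose (adjusted p = 2.17e-09), including H2-Ab1 (4.45 ± 0.27) and H2-Eb1 (5.05 ± 0.30). Complement genes rose in 9 of 12 cases and fell in 2 (adjusted p = 3.85e-08), with C4b (6.08 ± 0.23) and Cfb (5.52 ± 0.25) among the former. These 4 lists also passed with an estimated correlation.

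Chemokine ligands rose in 15 of 18 cases and fell in 1 (adjusted p = 5.63e-14), including Ccl7 (log2 fold change 7.53 ± 0.37 SE), Cxcl14 (6.24 ± 0.30) and Cxcl16 (6.48 ± 0.33). Inflammatory genes rose in 13 of 15 cases (adjusted p = 1.68e-05), such as Cxcl2 (4.66 ± 0.33) and Nlrp3 (2.61 ± 0.19). Alternative activation genes rose in 7 of 8 cases (adjusted p = 0.000754), with Mrc1 (5.24 ± 0.29) and Mgl2 (3.68 ± 0.20) higher and Chil3 lower (-6.98 ± 0.50). Among immune checkpoint genes 6 of 11 rose (adjusted p = 0.00405), among them Cd274, which encodes PD-L1 (3.44 ± 0.34), and Havcr2 (5.03 ± 0.37). Of 11 hypoxia genes 8 rose (adjusted p = 1.47e-05), including Vegfa (3.94 ± 0.19) and Hilpda (6.21 ± 0.34). All 5 lists passed with an estimated correlation. Immediate early and heat shock genes, which tissue dissociation can raise, moved with these groups. Of 16 such genes 10 rose and 2 fell, with Fosb (4.83 ± 0.26), Atf3 (4.70 ± 0.28), Nr4a1 (3.93 ± 0.26) and Hspa1a (5.04 ± 0.42) among the risers (adjusted p = 0.00117, and adjusted p = 0.16 with an estimated correlation). Tumors were digested with collagenase and marrow was not.

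Granule genes fell. All 16 specific granule genes were lower (median log2 fold change -8.42, adjusted p = 2.63e-46, and adjusted p = 0.00192 with an estimated correlation), as were 9 of 10 primary granule genes (adjusted p = 1.23e-15, and adjusted p = 0.00192 with an estimated correlation). The 1 primary granule member that rose was the chaperone gene Calr (1.64 ± 0.18 SE), which is not specific to granules. Monocyte genes fell in 9 of 12 cases and rose in 3 (adjusted p = 3.76e-06, and adjusted p = 0.0357 with an estimated correlation), with Ly6c2 lower by 7.12 ± 0.34 on the log2 scale. Ly6c2 is also among the sort antigens, so the gates favor its fall. Proliferation genes fell in 20 of 22 cases, such as Mki67 (-2.45 ± 0.19) and Plk1 (-2.55 ± 0.18), with a list adjusted p = 3.25e-06, and adjusted p = 0.0519 with an estimated correlation. Among 11 genes of the DNA methylation machinery 5 fell, including the maintenance methyltransferase Dnmt1 (-1.28 ± 0.19) and Uhrf1 (-1.33 ± 0.21), and 2 rose (list adjusted p = 0.145). With fry that list had an adjusted p = 1.04e-06. The transcription factor list had 20 higher and 10 lower of 37 (adjusted p = 0.0329, and adjusted p = 0.0548 with an estimated correlation), with the granulocyte factor Cebpe lower (-7.40 ± 0.32). Without BMDM_T replicate 2 that list had an adjusted p = 0.0591.

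Further lists passed with the preset correlation but not with an estimated one. Resident macrophage genes rose in 9 of 10 cases (adjusted p = 7.42e-05, and adjusted p = 0.0964 with an estimated correlation), with Mrc1 and Gas6 (5.75 ± 0.38 SE) among them, and lipid-associated macrophage genes in 8 of 12 (adjusted p = 0.00197, and adjusted p = 0.0964 with an estimated correlation), with Trem2 (4.2 ± 0.19) and Spp1 (4.79 ± 0.44). Angiogenesis and matrix genes rose in 15 of 17 cases (adjusted p = 9.74e-06, and adjusted p = 0.0524 with an estimated correlation), although the neutrophil proteases Mmp8 (-8.22 ± 0.61) and Mmp9 (-6.50 ± 0.38) fell. Interferon gamma genes rose in 11 of 14 (adjusted p = 0.000754, and adjusted p = 0.227 with an estimated correlation). Type I interferon genes rose in 9 and fell in 2 of 14 (adjusted p = 0.0426, and adjusted p = 0.471 with an estimated correlation), and this call was lost without BMDM_T replicate 2 (0.0591), BMDM_T replicate 4 (0.0532), TAM replicate 1 (0.0526) or TAM replicate 3 (0.0841). With camera, glycolysis (adjusted p = 0.458), lipid handling (0.15) and the sort antigens (0.329) did not pass as lists. With fry they did (adjusted p = 0.00761, 3.54e-05 and 0.000644). Within the last, Adgre1 rose 14.0-fold (adjusted p = 1.47e-10), Ly6c2 fell 139-fold and Ly6c1 fell 16.4-fold. Itgam (434 against 558 CPM, adjusted p = 0.0555) and Ptprc (adjusted p = 0.336) did not pass. The result for Itgam lay close to the threshold, and it passed in most alternatives, with an adjusted p = 0.0245 with DESeq2, 0.0353 with limma-voom, 0.044 without the low-count filter, 0.043 with a filter at 10 CPM, 0.0371 with only the libraries of these groups, 0.0146 after thinning, 0.0448 with scaling on other genes, 0.0481 without BMDM_H replicates 3 and 4, and 0.0437 with the replicate number as a block. Without 1 of the BMDM_H libraries it had 0.0415 (replicate 1), 0.0453 (replicate 2), 0.0443 (replicate 3) or 0.0454 (replicate 4).

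Of 7518 genes 4426 differed between TAM and BMDM_T, 2266 higher and 2160 lower in TAM (2622 and 1849 with total counts as the only scaling), and 21 of 27 lists passed, of which 12 passed with an estimated correlation. The groups differ in tissue, gate and digestion at the same time, so these cannot be separated in this comparison.

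**Figure D3:**
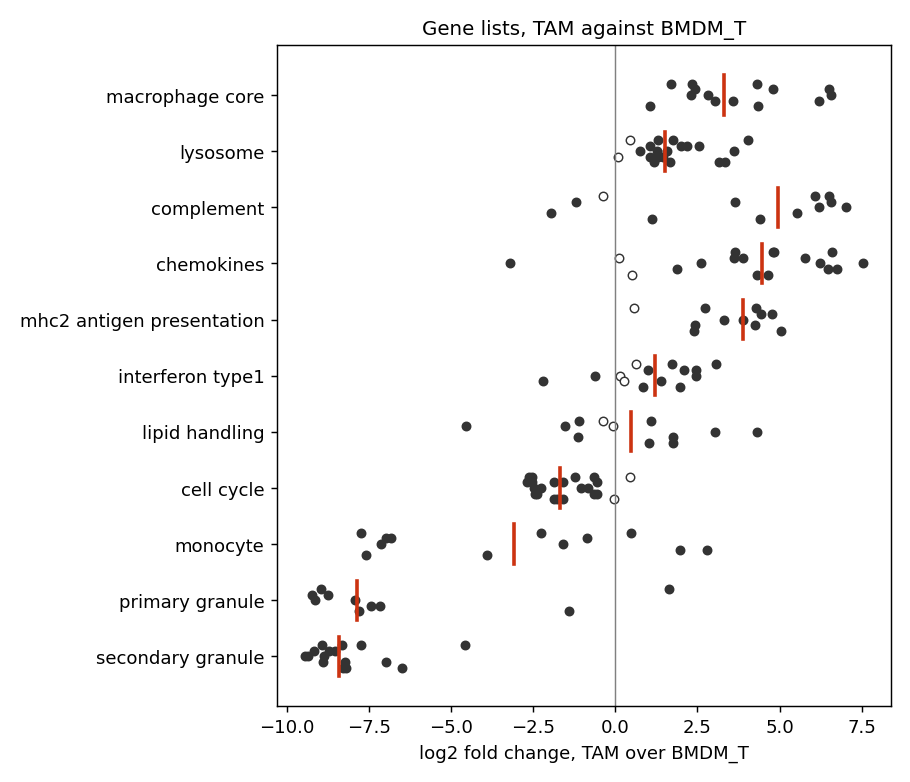
Log2 fold change of TAM over BMDM_T (horizontal axis) for each tested member of 11 gene lists, with filled points for genes with an adjusted p under 0.05, open points for the rest and a red bar at the list median. The macrophage core median lies at 3.31 and the secondary granule median at -8.42.

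Of the markers of other cell types, those of B cells, eosinophils, mast cells and basophils were scarcer in TAM than in marrow. The T cell sum was lower as well, mainly through 1 gene, Cd3d. B and plasma cell genes fell in 4 of 4 cases in TAM (adjusted p = 0.00034, and adjusted p = 0.0651 with an estimated correlation), with a median log2 fold change of -6.45 when the 2 genes without TAM counts are set at their bound. The same list had 1 higher of 4 in BMDM_T against BMDM_H (adjusted p = 0.0563), Mzb1, with an adjusted p = 0.469 with an estimated correlation. It passed with replicate blocks (adjusted p = 0.0112) and in 8 of the 11 fits with 1 library left out, such as 0.0102 without BMDM_T replicate 4. Erythroid markers differed in 2 of 5 cases between TAM and BMDM_T (adjusted p = 0.896), and megakaryocyte and platelet markers in 4 of 4, 3 of them lower (adjusted p = 0.655). Of these, Ppbp had an adjusted p = 0.203 with DESeq2, 0.354 with limma-voom, 0.0623 against a fold of 1.5, 0.0863 without TAM replicate 2, 0.0969 without TAM replicate 3 and 0.0529 without BMDM_H replicates 3 and 4. The 1 that rose was Pf4 (576 ± 269 against 38.3 ± 14.2 CPM), which is also in the resident macrophage list. The megakaryocyte and platelet list did not pass in BMDM_T against BMDM_H (adjusted p = 0.472). Lists with fewer than 4 tested members are given as summed CPM. Eosinophil markers summed to 299 ± 106 (SD, n = 4) in BMDM_H, 221 ± 87.1 (n = 4) in BMDM_T and 0.905 ± 0.66 (n = 3) in TAM. For mast cells and basophils the sums were 75.7 ± 17.9, 114 ± 58.8 and 1.05 ± 0.907, and for T cells 210 ± 57.2, 136 ± 17.6 and 14.2 ± 4.76. The only natural killer cell marker with a symbol, Klrk1, had 3.57 ± 1.41, 0.63 ± 1.26 and 14.6 ± 8.63 CPM, and dendritic cell markers summed to 24.9 ± 11, 17.7 ± 1.73 and 30.4 ± 16.1, with overlap between libraries of TAM and marrow. Epithelial and tumor cell markers summed to 54.8 ± 23.6, 36.3 ± 11 and 98.4 ± 19.7, with overlap between BMDM_H replicate 4 (80.7) and TAM replicate 1 (79.5). Fibroblast markers summed to 26.0 ± 24.6, 11.1 ± 6.80 and 33.9 ± 17.9, again with overlap. Endothelial markers summed to 34.4 ± 2.56, 38.7 ± 6.40 and 126 ± 15.7, and adipocyte markers to 7.84 ± 4.17, 13.9 ± 4.32 and 0.617 ± 0.854. Single genes carried several sums. Pecam1 and Eng made up most of the endothelial sum in TAM (62.2 ± 18.4 and 54.1 ± 12.5 CPM), where Egfl7 was lower than in marrow (1.37 ± 1.29 against 7.62 ± 1.67 in BMDM_H and 6.01 ± 1.28 in BMDM_T), and the adipocyte sum in BMDM_T was Retn alone. Transcripts of the mitochondrial genome and of milk-secreting epithelium were not analysed here.

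TAM against BMDM_H was added after the data had been examined. These groups differ in tumor, label age, tissue, gate and digestion at the same time, which cannot be separated. Of 7518 genes 4230 differed, 2103 higher and 2127 lower in TAM, and 22 of 27 lists passed, of which 12 passed with an estimated correlation. Zmynd15 rose 211-fold, Arg1 139-fold, Cxcl16 107-fold, the matrix protease Mmp14 81.0-fold, C4b 80.6-fold and Htra3 77.1-fold. Zmynd15 (70459433 to 70466202, plus strand) and Cxcl16 (70453983 to 70459984, minus strand) overlap on chromosome 11, and whether reads of 1 were counted for the other was not analysed here. Within the same limits on counts, Ltf fell 689-fold, Ngp 596-fold, Camp 513-fold, Lcn2 498-fold, Cd177 487-fold and S100a8 348-fold. The placental growth factor gene Pgf, Crym and Spon1 had 0 counts in BMDM_H and were at least 82.2-fold, at least 60.5-fold and at least 45.8-fold higher in TAM, whereas Prg2, Orm1 and Prss34 had 0 counts in TAM and were at least 566-fold, at least 232-fold and at least 229-fold lower. Of the 11 hypoxia genes 10 rose (adjusted p = 3.97e-08), with Mif higher by 3.98 ± 0.20 SE. Of the 16 dissociation and stress genes 8 rose and 2 fell (adjusted p = 0.00547, and adjusted p = 0.225 with an estimated correlation). Among the sort antigens Adgre1 rose 6.42-fold, Ly6c2 fell 239-fold and Ly6c1 30.2-fold, and Ptprc did not pass (adjusted p = 0.955). The gates favor the directions of Adgre1 and the Ly6c genes here as well. Itgam was lower (adjusted p = 0.0313), but not without TAM replicate 2 (0.0993), BMDM_H replicate 3 (0.0794), TAM replicate 1 (0.0597), BMDM_H replicate 2 (0.0545) or TAM replicate 3 (0.0538).

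MGM against BMDM_H compares mammary gland macrophages with the healthy marrow cells of batch 2, with 2 libraries against 4 and without gene names. Of 10615 rows tested 2733 differed, 1575 higher and 1158 lower in MGM. Leaving out MGM replicate 2 gave 1135 calls and leaving out MGM replicate 3 gave 1105, where the lone MGM library was assumed to vary like the others. The balance of directions depended on the method. With total counts as the only scaling 2537 rows were higher and 894 lower, with DESeq2 1333 and 1437, without BMDM_H replicate 6 1951 and 2033, and after thinning 738 and 774. The most abundant row took 13.7% to 16.7% of the counts in BMDM_H of batch 2 and 4.51% to 5.55% in MGM. TAM could not be set against MGM, because their batches list genes in different row orders.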

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

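Apart from the search for single far values, the splits of libraries and the fits with 1 library left out, all tests in this part were chosen after the result they bear on had been seen. For the correlation among erythroid genes, the primary granule list without 1 library and the depth test of Ptprc, the expectation was also written after values bearing on it had been seen.

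In each group of 4 libraries, a value was singled out when 1 library lay far from the other 3. Of 423 sets of values checked 19 met this, where the nominal rate of the rule for independent normal values gives about 21.1. Counts need not follow that rate, so the near match does not show that these values arose by chance. In BMDM_T replicate 1, CPM was highest for Arhgdib (4130, others 2780 to 2980), Ctsd (3050, others 2050 to 2170), S100a8 (37000, others 24500 to 26100) and Slc4a1 (1.08, others 0). In BMDM_T replicate 2 it was highest for Ppbp (18.5, others 0 to 2.31), Socs2 (22.7, others 8.61 to 10.4), Alas2 (0.84, others 0) and Ermap (0.84, others 0). Spon1 had 1.15 CPM in BMDM_T replicate 3 and Pgf 1.8 in BMDM_T replicate 4, against 0 in the others. In BMDM_H replicate 4, C1qc (252, others 99.7 to 112), Dhcr7 (10.4, others 1.59 to 1.86), Pmvk (57.3, others 25.7 to 30.2) and Saa3 (13.0, others 1.61 to 2.39) were high and Prss34 was low (31.2, others 106 to 116). H2-D1 (3460, others 2560 to 2630) and Ifitm6 (1260, others 789 to 851) were high in BMDM_H replicate 1, Calr (530, others 348 to 367) in BMDM_H replicate 2 and Nos2 (1.86, others 0) in BMDM_H replicate 3.

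The calls were compared with other splits of the same libraries. For BMDM_T against BMDM_H, 1 of the 35 splits, the real one, gave as many calls (362), and the highest other split gave 3. Of the 8 splits that part each pair of replicate numbers, the highest other gave 1. For TAM against BMDM_T, 1 of 35 splits gave as many as 4426, and the highest other gave 1522. For TAM against BMDM_H, 1 of 35 gave as many as 4230, and the highest other gave 2310. Were the calls due to chance, many splits would give as many, and only the real one did. However, 1 of 35 is the smallest share such a test can reach. For BMDM_T against BMDM_H it is 1 of 8 among the splits that part each pair. The difference between the real groups also adds to the spread within the groups of a wrong split, which lowers its calls. The splits alone therefore cannot exclude chance. In both comparisons with TAM, only 4 other splits gave any call, those that set 3 marrow libraries against the 3 TAM libraries and the fourth marrow library, and the other 30 gave 0.

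Erythroid genes were lower in BMDM_T. Loss of depth was set to bring the median of the 5 members above -1. It was -4.12 on the log2 scale after thinning to 1 total without a low-count filter. However, BMDM_T was not the shallower group, with a median total of 1096270.5 counts against 842058.5 in BMDM_H of batch 1. Thinning could therefore hardly have met that limit, and no conclusion on depth is drawn from it. A single library does not account for the lower values, since the median ran from -6.07 to -4.98 with any 1 of the 8 libraries left out. A lower share of red cell precursors in the BMDM_T libraries stays open. The median pair of members had a Spearman correlation of 0.8 across the 4 BMDM_H libraries, which such a mixture would give. However, this rests on 4 libraries, and a CD11b+ Gr1+ gate should leave such cells out. The erythroid sum was also lowest in BMDM_H replicate 1 (51.7 CPM, 1286844 counts) and highest in BMDM_H replicate 4 (260.2 CPM, 387940 counts). In replicates 2 and 3 it was 156 and 148.8 CPM. The correlation may therefore follow library totals as well as a mixture. Whether their number in marrow or the yield of lysis and sorting differed was not tested.

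Primary granule genes were higher in BMDM_T. A few abundant genes setting the scaling would bring the list median near 0, and it was 1.13 with factors from other genes. However, the TMM factors of batch 1 ran only from 0.91 to 1.11. Other factors thus had little room to move a median of 1.12, and the outcome was close to fixed beforehand. A single library does not account for the rise, since the median was at least 1.06 with any 1 of the 8 libraries left out. After thinning the median was 1.29. On average, thinning keeps the ratio of abundant genes such as Prtn3, so this says little on depth. A larger share of granulocyte or monocyte precursors in the sorted cells and a change within those cells were not tested. The label ages of 8 and 12 weeks go with the groups and cannot be told apart from the tumor.

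Ptprc, which encodes CD45, had 3 counts in BMDM_T replicate 1 and 82 to 143 in the other BMDM_T libraries. At their mean share 99.7 counts would be expected there, which argues against depth. Leukocyte genes were not missing, with a median log2 ratio of 0.12 over 11 members, which argues against fewer leukocytes. Only 0.25% of genes at 40 CPM or more lay 8 times or more below the other libraries, 8 genes including Rps2 and Slfn4, against 0.03% to 0.19% in the other BMDM_T libraries, so no wide class of genes was missing. No further explanation was tested, and the source of the low count stays open.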

How the results depend on the processing

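Chosen after seeing the data were thinning, leaving out the 2 shallowest libraries, scaling on other genes and every setting of TAM against BMDM_H. No named gene or list that was called reversed its direction under any alternative run. For BMDM_T against BMDM_H, 362 calls became 107 against a fold of 1.5, 233 after thinning to the smallest total (5240 genes tested) and 179 without the 2 shallowest libraries, and 238 to 409 with 1 library left out, of which the lowest was without BMDM_H replicate 2. TAM against BMDM_T gave 4107 to 4450 calls with 1 library left out and 2795 after thinning. TAM against BMDM_H gave 3815 to 4297, with 2702 against a fold of 1.5 and 2717 after thinning. MGM against BMDM_H gave 1105 to 3984 rows, the highest without BMDM_H replicate 6, and 1512 after thinning. Thinning tests fewer genes at lower depth, the treat test asks for a larger effect, and the cause of the other changes was not tested. With an estimated correlation the lists passing fell from 9 to 3, from 21 to 12 and from 22 to 12 in the 3 batch 1 comparisons. With fry 8, 25 and 26 of the 27 lists passed in these comparisons. Total counts only moved the median log2 fold change of all genes from -0.01 to -0.12 for BMDM_T against BMDM_H, from 0.03 to 0.18 for TAM against BMDM_T and from 0.18 to 0.61 for MGM against BMDM_H. With replicate numbers as a block, BMDM_T against BMDM_H gave 510 calls (355 shared with 362), TAM against BMDM_T 4544 and TAM against BMDM_H 4411, and the block ended the call of Fabp4 in the first (adjusted p = 0.0509) and changed no other call of a named gene there. For TAM, libraries share only a number. Batch terms and blocks between TAM and MGM, the tissue step difference, the batch difference and the overlap were not run, since rows cannot be matched across batches. The fit of MGM with BMDM_H held only those libraries from the start. Depth limits low genes, with 3 counts equal to 7.73 CPM in BMDM_H replicate 4 and 0.80 in TAM replicate 3.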

Other observations

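The gene lists described here were chosen after the calls had been seen. Iron handling genes rose in TAM against BMDM_T in 7 of 9 cases and fell in 1 (adjusted p = 0.00271, and adjusted p = 0.033 with an estimated correlation). The transferrin gene Trf reached 2480 against 208 CPM (log2 fold change 3.58 ± 0.21 SE) and the ferritin gene Fth1 11570 against 2769 CPM (2.06 ± 0.21). MHC class I genes rose in 9 of 10 cases (adjusted p = 0.00545, and adjusted p = 0.0627 with an estimated correlation), with H2-K1 (2.06 ± 0.23) and Tap1 (1.63 ± 0.16) among them. Genes of the unfolded protein response rose in 9 of 12 (adjusted p = 0.0161, and adjusted p = 0.195 with an estimated correlation), such as Hspa5 (2.29 ± 0.32). Ribosomal protein genes rose in 40 of 72 and fell in 3 (adjusted p = 0.0128, and adjusted p = 0.371 with an estimated correlation). General leukocyte genes fell in 7 of 11 and rose in 1 (adjusted p = 0.00271, and adjusted p = 0.033 with an estimated correlation), with Rac2 (-4.03 ± 0.20) and Cd37 (-4.27 ± 0.25) lower in TAM. Proteasome (adjusted p = 0.0842), cholesterol synthesis (0.0842) and oxidative phosphorylation (0.236) lists did not pass. In TAM against BMDM_H these lists passed with camera (adjusted p = 0.0104, 0.0208 and 0.0177). With an estimated correlation they had 0.0344, 0.147 and 0.321 there.

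Antioxidant genes went both ways in TAM. Gsr (-3.09 ± 0.25 SE), G6pdx (-2.98 ± 0.24) and Gclm (-2.66 ± 0.25) fell while Srxn1 rose (3.05 ± 0.34), and the list did not pass (adjusted p = 0.258). In BMDM_T against BMDM_H, Gclm (1.25 ± 0.22) and G6pdx (0.92 ± 0.20) were higher, without a call for the list (adjusted p = 0.131), and G6pdx had an adjusted p = 0.142 without BMDM_H replicates 3 and 4. Of the 9 added lists, oxidative phosphorylation passed there (4 of 74 higher, adjusted p = 0.00447, and adjusted p = 0.34 with an estimated correlation), led by Atp5k (0.77 ± 0.17). The other 3, Cox7b, Cox7a2 and Uqcr11, did not pass with total counts only (adjusted p = 0.0591, 0.0835 and 0.123), nor without BMDM_H replicate 1 (0.0698, 0.112 and 0.108), BMDM_H replicate 2 (0.0642, 0.117 and 0.12) or BMDM_T replicate 2 (0.0861, 0.1 and 0.0789), and none of the 4 passed against a fold of 1.5.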
